A study of Homo sapiens with 25 samples.

How the data were processed

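Chromatin immunoprecipitation sequencing was done in MDA-MB-231 cells fixed with disuccinimidyl glutarate and formaldehyde, with PML silenced by lentiviral short hairpin RNA where stated, per the labels' protocols. Reads were aligned to hg38, and BWA 0.7.12-r1039, Picard 1.104, MACS2 2.2.7.1 and deepTools are named in the submitters' processing notes without a role. The domain lists gave 1 score per domain in the deposited files, with no unit stated, and the caller is named only in the file names, as EDD. The peak lists gave a fold enrichment per peak, a ratio, in the deposited MACS2 layout. They also gave a -log10 q-value per peak in the deposited files, with a lowest value of about 1.3 in each list. Peaks were called on replicates 1 and 2 together, per the peak names in the deposited lists. Whether domains were called on pooled replicates is not given in the sources used here, but each target and condition has 1 list. The peak files mark conditions as ct and pml, read here as control and PML knockdown because no other condition of the labels fits; this reading is an assumption. Read depth is unknown, so precision could not be derived from counts. Domain bounds lie on grids of 9 kb for PML, 17 and 22 kb for LMNB1 and 23 and 35 kb for H3K9me3 (control and knockdown), so the lists differ in resolution.

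Groups followed the labels. H3K27me3 and input libraries were not analysed here, and the inputs have no list. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and bedtools 2.31.1 for a check of overlap calls. Domains were compared in 1 kb bins of chromosomes 1 to 22 and X after removing assembly gaps of at least 10 kb, which left 2912 Mb. Genes were the 19970 protein-coding genes of GENCODE release 44 on these chromosomes, and a promoter was the start of the Ensembl canonical transcript with 1 kb on either side. Peaks were shared when they overlapped by 1 bp. A promoter counted as marked in 1 list only when it held a peak of that list, none of the other list, and no peak that overlapped one of the other list outside the promoter.

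Tests, alternatives, gene lists and the rule for named genes were fixed before the data were examined, except where stated. Overlap of PML domains was tested with 10000 circular shifts within each chromosome (one-sided). Retention inside against outside PML domains was tested with 10000 rotations of the PML label along the joined control domains, and the position of changed peaks with 10000 circular shifts (both two-sided). P-values were adjusted by Benjamini-Hochberg within each family. These tests concern positions of the lists and not replicates. Errors are delete-one-chromosome jackknife SEs, which measure spread along the genome. The 16 gene lists and 10 gene families were compared with 10000 random lists holding as many members marked, for losses, or unmarked, for gains, in the control list. Their percentiles describe these lists, and with 26 lists, both marks and both directions some fall outside the central 95% by chance.

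Named genes were, per mark, the 10 with the highest fold enrichment of a promoter peak in 1 list only, and up to 4 such members of each fixed list. For domains they were up to 4 genes of the 5 longest PML domains and of the 5 longest stretches lost and gained, members of the fixed lists in PML domains or in a domain of 1 condition only, and PML and LMNB1. A stretch and a list count that fell under this rule were left out of the text. Alternatives were domains of at least 500 kb, joining within 100 kb, autosomes only, other null placements, stricter or equal-sized peak lists, other definitions of sharing and promoters of 500 or 2500 bp on either side. Percentiles of list members in PML domains among circular shifts, mean GC of domains, promoters changed at both marks, and all adjustments for GC content or peak rank, were added after the data were seen. Regional GC is the mean over the surrounding 500 kb, and standardised differences weight its deciles by length. In the peak comparison, shared peaks were weighted to the other peaks in 20 bins.

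The tests were run on simulated lists. With PML-sized domains placed at random on linear chromosomes, 16 of 100 overlap tests gave p under 0.05, and with the placement rotated at random 5 of 100 did; with overlap planted, 100 of 100 did. A randomly rotated list differs from its own shifts only by another random shift, so about 5 of 100 was fixed by design. It therefore cannot show what caused the 16 of 100. Coverage of the outer 5% at each end was 0.304 of the mean for PML and 0.509 and 0.472 for control and knockdown LMNB1. Whether avoidance of ends gave the excess was not tested. Given the 16 of 100, the p for PML with LMNB1 may be too small by an unknown amount. H3K9me3 lay at ends more than elsewhere, 1.43 and 2.86 of the mean, and PML with H3K9me3 was not simulated. Random placement is given beside both. A planted retention difference of -21.3 points was recovered as -21.2 on average, with 100 of 100 tests under 0.05, against 3 of 100 with none planted. For peaks in domains the counts were 100 of 100 and 1 of 100. In the retention simulation whole domains were kept independently of one another. In the data retention followed regional GC, so the retention counts do not give the error rate for the deposited lists. Overlap calls matched bedtools for 5000 of 5000 simulated intervals.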

Results

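The series profiled chromatin in MDA-MB-231 cells, a human triple-negative breast cancer line that is highly metastatic in mice. Chromatin immunoprecipitation followed by sequencing was run for PML, the scaffold protein of PML nuclear bodies, in libraries whose titles name the line and no condition. No PML library was titled as knockdown, so the PML domains have no knockdown check. Lamin B1 (LMNB1), a protein of the nuclear lamina, and histone marks were profiled in control cells and in PML knockdown cells. The knockdown used a lentiviral short hairpin RNA. The 25 libraries comprised 3 of PML, 2 of each of LMNB1, H3K9me3, H3K27me3, H3K4me3 and H3K27ac in each condition, and 1 input per condition. The 9 lists used here gave 1 list per target and condition: 5 lists of broad domains (PML, and LMNB1 and H3K9me3 in both conditions) and 4 lists of peaks (H3K4me3 and H3K27ac in both conditions). The 4 H3K27me3 libraries were not analysed here. No list held a value per replicate and the read depth is unknown, so no difference between conditions below has a replicate check. A peak or domain missing from a list was below the authors' threshold, which is not absence. PML itself (ENSG00000140464.20, chromosome 15, 73994673 to 74047827, hg38) carried a promoter peak of H3K4me3 and of H3K27ac in both lists, with fold enrichments of 21.9 and 4.11 in the control lists and 58.3 and 11.3 in the knockdown lists. Folds of separate lists are not on a common scale, and at LMNB1 they were 21.6 and 15.2 against 22.2 and 13.8. Peaks shared between the lists had median folds of 10.5 and 5.98 in the control lists and 20.8 and 7.88 in the knockdown lists. A hairpin acts on the transcript, so the peaks at PML do not measure the knockdown. LMNB1 also had promoter peaks of both marks in both lists, and neither gene started inside a PML, LMNB1 or H3K9me3 domain.

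PML covered broad, gene-poor domains that lay, for most of their length, within lamin-associated chromatin. The PML list held 420 domains spanning 970.2 Mb, 33.3% of the gap-free genome, with a median length of 1040 kb. None lay on chromosome X, where the control LMNB1 and H3K9me3 lists also held little, 1.00 and 5.75 Mb. Of the PML domain length, 89.6% ± 1.38 (SE, jackknife over chromosomes) lay in control LMNB1 domains, and 42.9% ± 5.07 lay in control H3K9me3 domains, H3K9me3 being the mark of constitutive heterochromatin. By number, 345 of the 420 domains were covered to at least 50% by control LMNB1 and 71 had no overlap with it. Olfactory receptor genes were common inside, and no HOX gene, clustered protocadherin or gene of the housekeeping list started in a PML domain.

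The comparison asked where PML sits relative to the lamina and to heterochromatin in the control lists. Circular shifts of the PML domains gave a mean of 38.1% for LMNB1 and 23.8% for H3K9me3, so the observed shares were 2.35 and 1.81 times the shifted ones (one-sided permutation p = 0.0001 for each, the smallest that 10000 shifts can give, and 0.000111 after Benjamini-Hochberg adjustment over 10 pairs of lists). PML and LMNB1 both avoided chromosome ends, which the shifts do not keep, and in simulations with no relation 16 of 100 tests of PML-like lists against LMNB1 gave p under 0.05. Random placement on linear chromosomes gave 2.30 and 1.81 times (permutation p = 0.0001 for each). At equal regional GC content, LMNB1 coverage was 79.3 ± 2.29 percentage points higher inside PML domains than outside, and H3K9me3 coverage 55.0 ± 3.51 points higher; without this adjustment the differences were 82.9 ± 1.66 and 32.0 ± 5.40 points. The parts covered by neither list came to 85.1 Mb, 8.77% of the PML length.

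The longest PML domain ran from 70020001 to 92826000 on chromosome 12 (22.8 Mb, 66 protein-coding genes from CNOT2, KCNMB4, PTPRB and PTPRR onward). Others lay on chromosome 1 from 68391001 to 88839000 with RPE65, which encodes the retinoid isomerase of the eye, on chromosome 11 from 88011001 to 107568000 with TYR, the tyrosinase of melanin synthesis, on chromosome 13 from 53415001 to 72549000, and on chromosome 7 from 108567001 to 127566000 with LRRN3 and IMMP2L. LMNB1 covered between 92.4% and 99.3% of each of these 5. Of 19970 protein-coding genes, 2612 (13.1%) started in a PML domain. Among gene families the share was 74.5% of 415 olfactory receptor genes, 77.3% of 22 CEACAM and PSG genes, 59.7% of 149 keratin and keratin-associated genes and 35.8% of 509 ZNF genes, but 12.7% of 371 solute carriers, 15.9% of 44 collagens, 13.7% of 73 histone genes, and 0 of 39 HOX, 53 clustered protocadherin and 19 HLA genes. Circular shifts of the PML domains, which follow their length and not the density of genes, put the olfactory receptor count at percentile 99.6, solute carriers at 0 and collagens at 1.1. Within the central 95% of shifts lay CEACAM and PSG genes (88.3), keratins (81.5), ZNF genes (63.2), histone genes (30.7), clustered protocadherins (29.6), HLA (17.2) and HOX genes (5.32).

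Metastasis and mesenchymal genes started in PML domains about as often as circular shifts of the domains give. Among 20 genes tied to lung or bone metastasis in this line, 6 did: MMP1 and MMP2, which encode matrix metalloproteinases, TNC, VCAM1, PTGS2 and KYNU. Also starting in PML domains were 5 of 15 EMT genes (TWIST1, ZEB2, CDH2, CDH11 and PRRX1), 3 of 20 matrix genes (COL1A2, COL3A1 and TIMP3), 3 of 10 basal genes (CAV1, CAV2 and MET), 4 of 20 interferon response genes (IFI44, IFI44L, IFIH1 and TRIM22), and 4 of 13 immune and stromal markers, among them PTPRC and DCN. So did 2 of 17 inflammatory genes (CCL2 and CCL5), 2 of 13 stem cell genes (SOX9 and ALDH1A1), 2 of 20 luminal genes (PGR and FOXA1), and PLOD2, CCNE1 and FAS in the hypoxia, cell cycle and p53 lists. No PML body component, heterochromatin factor or housekeeping gene did. For metastasis genes the shifts gave a mean of 6.27 and for EMT genes 5.25, and both counts stood at percentile 46.5. Below the central 95% of shifts lay the luminal (percentile 0.665), hypoxia (0.155), cell cycle (0.38), p53 (1.24), PML body (0.09), heterochromatin (0.01) and housekeeping (0.08) lists. The shifts ignore gene density, so a list near the share of all genes can fall this low. The luminal list, at 10%, had a shift mean of 7.67 of 20. These percentiles therefore do not show depletion relative to other genes. The shares of 30% and 33.3% are above the 13.1% of all protein-coding genes, a difference for which no test was run.

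**Figure D1:**
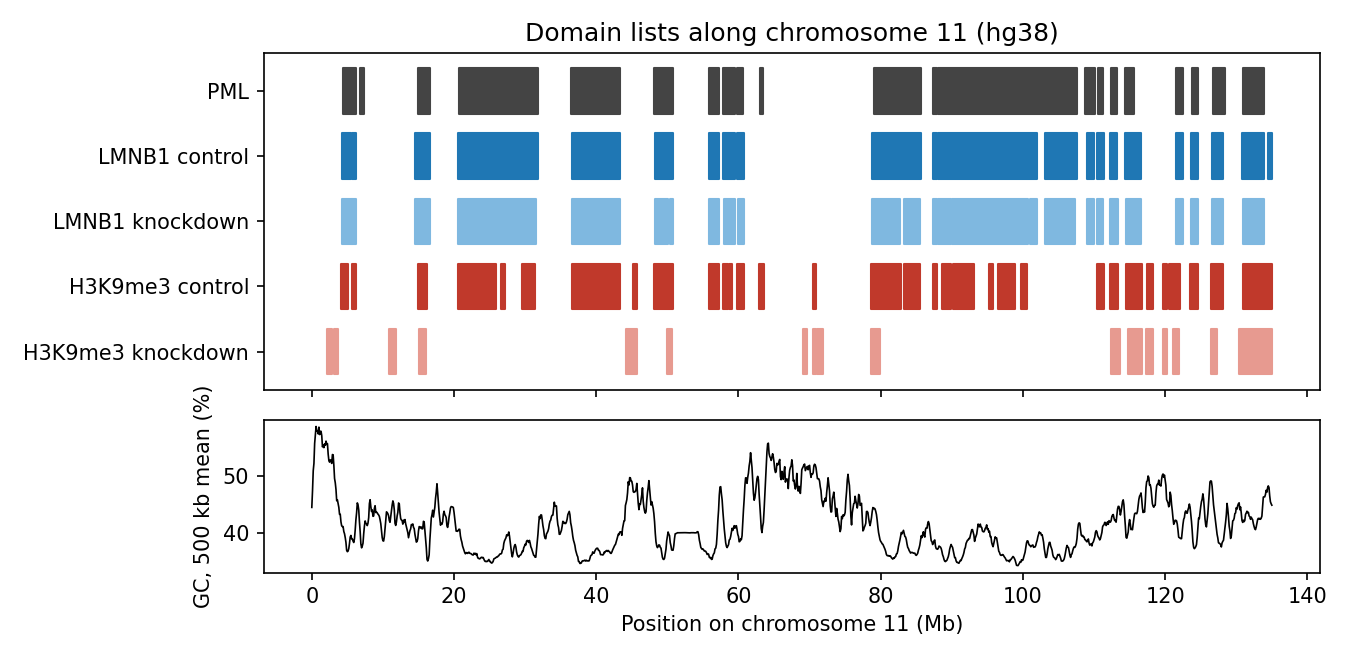
Domain lists along chromosome 11 (horizontal axis, position in Mb), with 1 row per list above and the regional GC content in percent (500 kb mean) below. PML and both LMNB1 lists follow each other, whereas 39.8 Mb of control H3K9me3 domain on this chromosome is not in the knockdown list.

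LMNB1 domains were largely retained after PML knockdown. Of 998 Mb in 410 control domains, 90.4% ± 0.78 (jackknife SE) was also in one of the 380 knockdown domains, which spanned 947 Mb. The lists differed by 96.2 Mb lost and 44.5 Mb gained. The longest lost stretches held TWIST1, which drives epithelial-mesenchymal transition, and ADAMTS18, and the longest gained ones FLRT3 and TSLP.

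The longest lost LMNB1 stretch lay on chromosome 7 from 18986001 to 20655000 (TWIST1, FERD3L, POLR1F and TMEM196). Other long lost stretches lay on chromosome 16 from 77198001 to 78694000 (SYCE1L, ADAMTS18, NUDT7 and VAT1L), chromosome 3 from 59449001 to 60911000 with no gene start, and chromosome 7 from 111474001 to 112926000 (IMMP2L, DOCK4, ZNF277 and IFRD1). The longest gained stretches lay on chromosome 20 from 14278001 to 16500000 (FLRT3), chromosome 5 from 109846001 to 111996000 (TMEM232, SLC25A46, TSLP and WDR36), chromosome 3 from 109582001 to 111584000 (NECTIN3 and CD96), chromosome 4 from 30719001 to 32521000 (PCDH7), and chromosome X from 25168001 to 26774000 (MAGEB18, MAGEB6B, MAGEB6 and MAGEB5). Of 2468 genes that started in a control LMNB1 domain, 409 started outside the knockdown domains, among them TWIST1 and AURKA, and 132 genes started in gained domain.

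H3K9me3 domains shrank far more between the lists than LMNB1 domains. Of 629 Mb in 430 control domains, 44.6% ± 3.10 (jackknife SE) was also in one of the 281 knockdown domains, which spanned 361 Mb. Median domain scores were 27.6 in the control and 15.0 in the knockdown H3K9me3 list, against 52.8 and 47.1 for LMNB1. Scores of separate lists may not share a scale, and the knockdown H3K9me3 list has the coarser grid, 35 against 23 kb. A weaker set of calls in the knockdown list was not told apart from a loss of the mark. Olfactory receptor genes left the domains in bulk, from 278 to 60 of 415, with 221 lost and 3 gained. ZNF genes, many of which carry H3K9me3 in differentiated cells, went from 234 to 189, with 165 of them in both lists, and keratin genes from 108 to 100, with 33 lost and 25 gained. Among all protein-coding genes the number went from 1997 to 1718, with 959 lost and 680 gained. All 8 HLA genes that started in a control domain, all of class II, were outside the knockdown domains.

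In length, 348 Mb of control domain was lost and 80.6 Mb gained, and 200 control domains had no overlap with any knockdown domain. Lost sequence was AT-rich and gained sequence GC-rich: mean GC content was 38.2% ± 0.22 in lost, 43.6% ± 0.17 in kept and 46.7% ± 0.22 in gained domain, against 40.9% ± 0.37 genome-wide. The longest lost stretches were chromosome 2 from 75716001 to 83030000 (LRRTM4, REG3G, REG1B and REG1A), chromosome 21 from 18630001 to 25553000 (NCAM2), chromosome 11 from 36639001 to 43309000 (LRRC4C), chromosome 16 from 58765001 to 65345000 (CDH8 and CDH11, which encode cadherins), and chromosome 13 from 52716001 to 58765000 (CNMD, PCDH8, OLFM4 and PRR20A). The longest gained ones were chromosome 3 from 125615001 to 127540000 (ROPN1B, SLC41A3, ALDH1L1 and KLF15), chromosome 21 from 37520001 to 39165000 (KCNJ6, KCNJ15, ERG and ETS2), chromosome 5 from 169349001 to 170800000 (SPDL1, DOCK2, INSYN2B and FOXI1), chromosome 3 from 13615001 to 14945000 (WNT7A, CHCHD4 and TMEM43), and chromosome 1 from 229670001 to 230895000 (GALNT2, PGBD5, COG2 and AGT). Members of the fixed lists that started in lost domain were TNC, THBS1, CDH11, FOXA1, IFI44, IFI44L, CCL5, TBX15 and OTX2. Those in gained domain were CXCR4, a chemokine receptor, COL6A3, LAMB3, SNAI2, TWIST2, NDRG1, IFI27, MX1, MX2, CCND1, PLK1, VWF, CDH5 and FOXF1.

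The share of PML domain length in H3K9me3 domains was 42.9% in the control list and 13.7% ± 3.01 in the knockdown list, the latter 1.03 times its shifted mean (one-sided permutation p = 0.353). Knockdown H3K9me3 coverage was 1.99 ± 3.32 points higher inside PML domains than outside (two-sided permutation p = 0.708). At equal regional GC the difference was 29.1 ± 2.86 points (two-sided permutation p = 0.0001, the smallest possible), against 55.0 ± 3.51 points in the control list. The adjusted values weight GC deciles by length and not by where PML lies. PML domains had a mean GC of 37.6%, against 40.9% genome-wide, so the 29.1 points do not describe PML domains as a whole.

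The next comparison asked whether domains occupied by PML were retained differently from the rest. H3K9me3 was kept over 31.8% ± 4.76 of its control length inside PML domains and 69.8% ± 3.93 outside, a difference of -38.0 ± 5.97 percentage points (two-sided permutation p = 0.0001, the smallest that 10000 rotations can give). The direction held on 20 of 22 autosomes, chromosomes 19 and 22 being the exceptions. This difference was not present at equal regional GC content: standardised over deciles of the mean GC of the surrounding 500 kb, it was 3.02 ± 2.13 points (permutation p = 0.169). Kept shares went from 1.41% in the lowest to 93.4% in the highest decile of regional GC, and 99.3% of the lowest but 18.0% of the highest decile lay in PML domains. Of the gained length, 0.756 Mb of 80.6 Mb lay inside PML domains.

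LMNB1 differed in the opposite direction, with 93.7% ± 0.67 kept inside PML domains and 68.1% ± 3.49 outside, a difference of 25.6 ± 3.64 points (two-sided permutation p = 0.0001, the smallest possible). Standardised over regional GC it was 25.3 ± 14.1 points (permutation p = 0.0001), with an error much larger than before. The LMNB1 difference was not adjusted for domain score. In length, 54.9 of the 96.2 Mb of lost LMNB1 domain lay inside PML domains. The lost LMNB1 stretches named above, including the one with TWIST1, lay wholly inside them. H3K9me3 control length that was also in LMNB1 and PML domains was kept over 30.9%, that in PML without LMNB1 over 54.0%, that in LMNB1 without PML over 62.7%, and that in neither over 74.2%; these shares are not adjusted for GC.

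**Figure D2:**
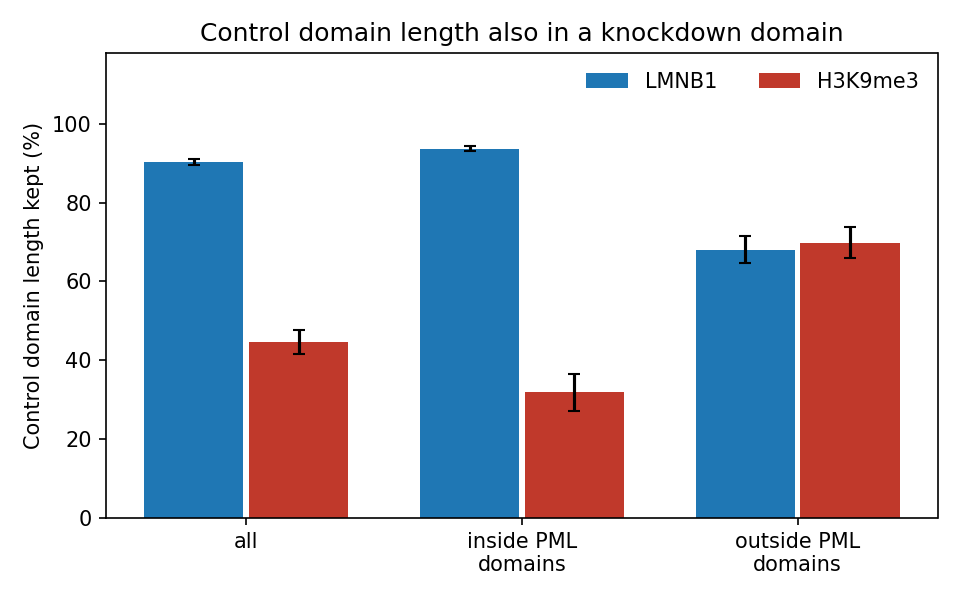
Percent of control domain length that is also in a knockdown domain (vertical axis), for LMNB1 and H3K9me3, over all domains and split by PML domains, with bars from 0 and error bars of 1 jackknife SE over chromosomes. H3K9me3 stands at 31.8% inside and 69.8% outside, and LMNB1 at 93.7% and 68.1%, before any adjustment for GC.

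**Figure D3:**
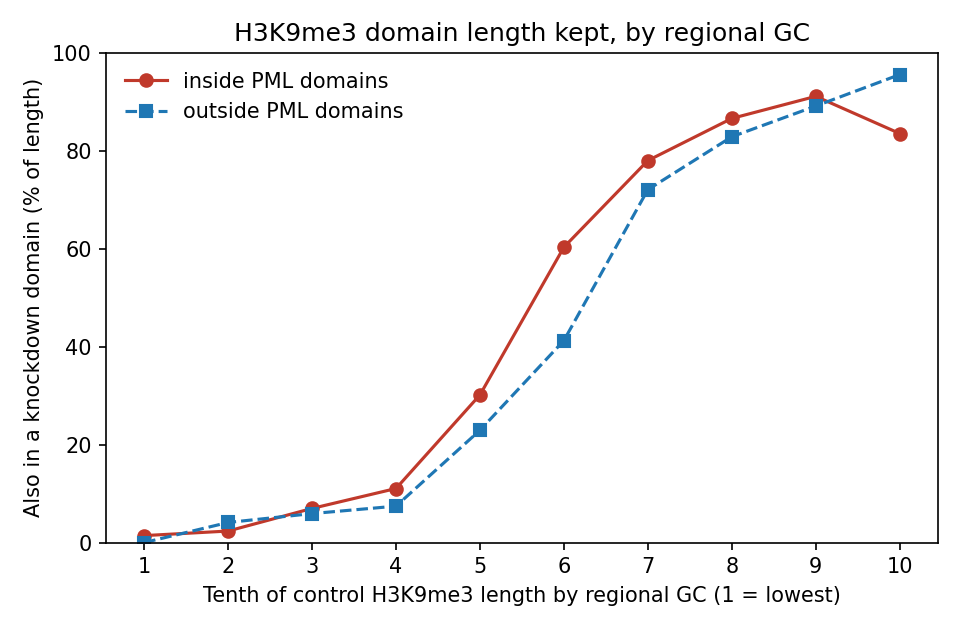
Percent of control H3K9me3 length also in a knockdown domain (vertical axis) by decile of regional GC content (horizontal axis, 1 is lowest), inside and outside PML domains. Both lines climb up to decile 9, with inside higher in decile 6 (60.3% against 41.3%) and lower in decile 10 (83.6% against 95.6%).

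H3K4me3, the mark of active promoters, was found at nearly all control sites after PML knockdown, and the knockdown list held many weaker peaks besides. Of 22211 control peaks on chromosomes 1 to 22 and X, 98.8% overlapped a knockdown peak and 260 did not. Of 27760 knockdown peaks, 7436 overlapped no control peak. Promoters marked in the knockdown list only numbered 357, led by PDE9A, a cyclic GMP phosphodiesterase, and MARCHF4, a ubiquitin ligase. Promoters marked in the control list only numbered 19, led by CD74, the MHC class II invariant chain, and RUNX2, a transcription factor of bone formation. Marked promoters came to 12347 and 12725 of 19970.

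Fold enrichment is the authors' own value for a peak and ranks peaks within 1 list. Within the knockdown list the promoter peaks without a control counterpart that had the highest fold enrichment were at PDE9A (18.2; chromosome 21, 42654249 to 42654847), MARCHF4 (15.7; chromosome 2, 216371910 to 216373509), PPP2R3B (15.6), NOL4L (14.8), POU2AF3 (12.6), FSTL4 (12.1), AVPR1B (11.6), a vasopressin receptor, CAMKK1 (11.5), ARHGAP20 (11.5) and ASCL2 (11.3), a transcription factor of intestinal stem cells. Within the control list they were at CD74 (6.02; chromosome 5, 150412533 to 150413187), RUNX2 (5.96; chromosome 6, 45328128 to 45328649), SMKR1 (5.11), LCTL (4.67), KLRC3 (4.38), KYNU (4.37), ESRRG (4.24), CDH12 (3.93), GPX7 (3.87) and SLITRK6 (3.68). RUNX2, KLRC3, KYNU, ESRRG, CDH12 and SLITRK6 started in PML domains, as did ARHGAP20. Peaks without a counterpart ranked low: their median rank was 14.9% from the bottom of the knockdown list and 6.94% in the control list, and 17 of 7436 and 6 of 260 lay above the median of their list. With equal numbers of peaks taken from both lists, 2611 and 982 had no counterpart. With 2500 bp on either side of the start, KLRC3 was no longer marked in the control list only. With 500 bp, PDE9A, POU2AF3, FSTL4 and ASCL2 held no knockdown-only promoter peak. With -log10 q of at least 5 in both lists, KLRC3, ESRRG, CDH12 and SLITRK6 dropped out.

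Among the fixed lists, H3K4me3 promoter peaks in the knockdown list only were seen at ANGPTL4, which promotes vascular permeability, for the metastasis genes, ITGB3 for matrix genes, PGR for luminal genes (not with 2500 bp around the start), CXCL8 and CSF2 for inflammatory factors, and CD68 for immune markers. Promoter peaks in the control list only were seen at KYNU and at GDF15, a p53 target. Of 9 unmarked inflammatory genes 2 were gained, at percentile 96.7 of random lists, and 1 with -log10 q of at least 5 or with equal numbers of peaks, where CSF2 and ITGB3 dropped out. ITGB3 also dropped out with 500 bp around the start, and PGR with equal numbers. No list or family lay above the central 95% of random lists for gains. Olfactory receptor genes, with 0 of 414, and keratins, with 1 of 144, stood at percentiles 0 and 0.47. For losses the metastasis and p53 lists stood at 99.1 and 99.2, each through 1 gene, and GDF15 dropped out with -log10 q of at least 5 in both lists. EMT, basal, hypoxia, interferon, stem cell and developmental genes had 0 changed promoters for this mark, and the PML body, heterochromatin, cell cycle and housekeeping lists were marked throughout in both lists. In the families the changes were 1 ZNF, 2 clustered protocadherin (PCDHAC1 and PCDHB1), 1 HOX (HOXB5), 1 HLA (HLA-DQB1), 2 CEACAM and PSG (CEACAM1 and PSG4) and 5 solute carrier promoters gained, and 0 histone or collagen promoters.

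H3K27ac, the mark of active promoters and enhancers, changed in both directions between the lists. Of 42320 control peaks 3559 (8.41%) overlapped no knockdown peak, and of 43615 knockdown peaks 6762 (15.5%) overlapped no control peak. Promoters marked in the knockdown list only numbered 647 and included 22 ZNF genes and the p53 targets CDKN1A, FAS and BBC3. Promoters marked in the control list only numbered 133, among them ZEB2, a repressor of E-cadherin, and the interferon-induced genes MX1 and OAS1. The changes at both marks coincided at 16 promoters in the knockdown direction and at 3 in the control direction. Independent lists spread over all protein-coding promoters would give 11.6 and 0.127. A gain can occur only at a promoter unmarked in the control list, and a loss only at a marked one. These values are therefore not a fair baseline, and whether the changes coincide more or less often than by chance was not tested.

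Promoter peaks without a control counterpart that ranked highest in the knockdown list were at ZNF658 (11.2; chromosome 9, 66900241 to 66901444), ACAP3 and PUSL1 (10.4, 1 shared peak), ZNF530 (10.0), TAF4B (9.83), CFAP77 (9.77), SLC39A11 (9.61), a zinc transporter, BTC (9.33), a ligand of the EGF receptor, SAMD5 (9.33) and STX7 (8.91). In the control list they were at MAPK3 (7.15; chromosome 16, 30123393 to 30123731), the kinase ERK1, ZNRF3 (6.65), PIAS2 and KATNAL2 (6.06, 1 shared peak), ACTR5 (5.73), ATRNL1 (5.59), PABPC4L (5.59), GM2A (5.48), TMEM131L (5.23) and INPP1 (5.22). The median rank of peaks without a counterpart was 14.8% from the bottom of the knockdown list and 12.8% in the control list. Peaks with -log10 q of at least 5 and no counterpart in the full other list numbered 2746 and 971.

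Of 137 ZNF promoters unmarked in the control list, 22 were marked in the knockdown list, against a mean of 9.06 and a central 95% range of 4 to 15 in random lists (percentile 99.995). The random lists were not matched for H3K4me3, which in the control list marked 434 of 509 ZNF promoters but 61.8% of all promoters. The percentile thus cannot tell a trait of ZNF genes from one of H3K4me3-marked promoters. In the other direction 5 ZNF promoters were lost (percentile 54.4). Of 7 unmarked p53 and senescence genes 3 were gained (BBC3, FAS and CDKN1A, percentile 99.6), though the CDKN1A peak had a fold enrichment of 1.68. Luminal genes gained EPCAM, ERBB2 and ERBB3 (percentile 96.2), and developmental factors gained SIX2 and GATA6 (81.7). HLA genes gained HLA-F, HLA-DMA and HLA-B (94.8), and CREBBP was gained for PML bodies (96.8). CXCL1, ITGA5, TGFB1, PDGFRB and CEACAM1 were also gained. Losses included ZEB2 and TGFBI of the EMT list (percentile 99.7), MX1 and OAS1 of the interferon list (98.8), KYNU, TP63, LMNB2, PCDHB9, HOXC5 and HPRT1. Solute carriers had 12 gained and 2 lost, and keratins 1 gained (KRT16, percentile 0.05). With -log10 q of at least 5 in both lists, the p53 gains, the EMT losses and the interferon losses came to 1 each. With 500 bp around the start, KATNAL2, ATRNL1, FAS, CDKN1A and ERBB3 dropped out. With 2500 bp around the start, ZEB2, KYNU and BBC3 were no longer marked in 1 list only, and BBC3 was not when peaks within 1 kb counted as shared. The hypoxia, cell cycle, inflammatory, stem cell, histone and collagen groups had 0 changed promoters, and olfactory receptors 0 of 414 gained.

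The last comparison asked whether peaks that differ between the lists lie in PML domains. Control peaks without a knockdown counterpart did so more often than shared peaks: 28.5% against 10.1% for H3K4me3, a difference of 18.3 ± 2.65 points, and 21.6% against 14.0% for H3K27ac, a difference of 7.56 ± 1.14 points (two-sided permutation p = 0.0001 for each, the smallest possible, adjusted p = 0.0002 over 4 tests). Against shared peaks weighted to the same regional GC, these differences were 1.97 ± 2.98 points (permutation p = 0.702) and -0.19 ± 0.84 points (permutation p = 0.925). Against shared peaks of equal -log10 q they were 12.5 points (permutation p = 0.0012) and 3.78 points (permutation p = 0.0011). Knockdown peaks without a control counterpart differed from shared ones by 2.22 ± 0.74 points for H3K4me3 (permutation p = 0.0535, adjusted 0.0612) and by -1.31 ± 0.66 points for H3K27ac (permutation p = 0.0612, adjusted 0.0612), neither past 0.05. Other choices passed it: for H3K4me3 2.45 points with -log10 q of at least 5 (permutation p = 0.0225) and 2.71 with sharing within 1 kb (permutation p = 0.0204), and for H3K27ac -1.80 with equal numbers of peaks (permutation p = 0.0130). Their signs were not stable: with equal numbers of peaks the H3K4me3 difference was -0.32 points (permutation p = 0.575), the H3K27ac difference was 0.59 with -log10 q of at least 5 (permutation p = 0.307), and against shared peaks of equal -log10 q the knockdown differences were -10.2 and -6.08 points (permutation p = 0.0001 for each).

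**Figure D4:**
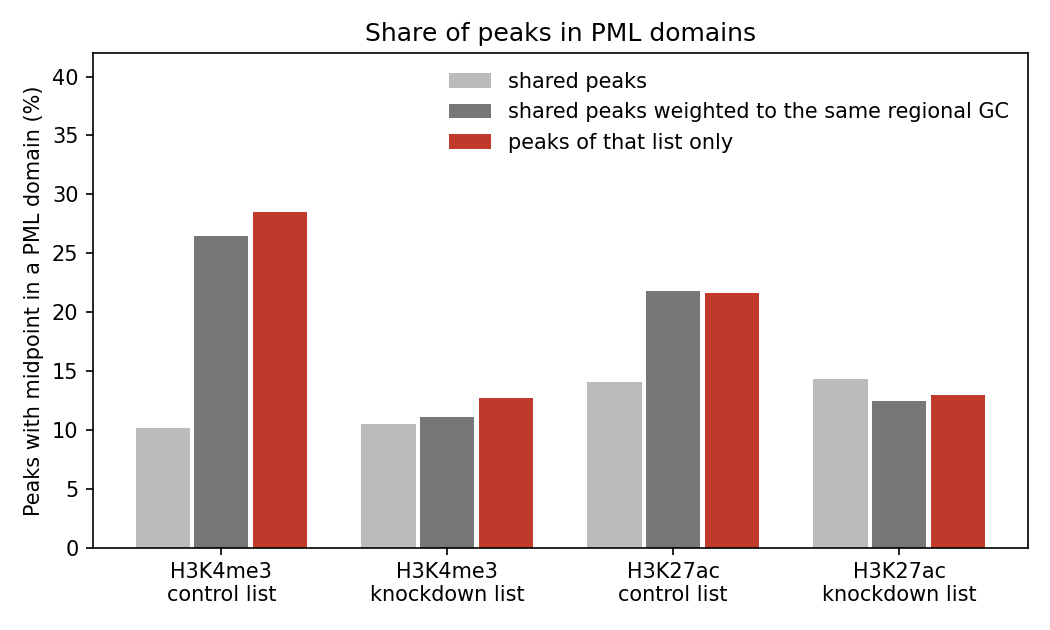
Percent of peaks whose midpoint lies in a PML domain (vertical axis) for each peak list, as bars from 0 for shared peaks, shared peaks weighted to the same regional GC, and peaks of that list only. For H3K4me3 control peaks the bars stand at 10.1%, 26.5% and 28.5%.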

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

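The peak lists also hold entries outside chromosomes 1 to 22 and X, which no comparison used: 73 in the H3K4me3 control list, 68 in the H3K4me3 knockdown list, 76 in the H3K27ac control list and 60 in the H3K27ac knockdown list. They were singled out as signal in data left out of the comparisons, above the 3 that a count of 0 allows, and were not examined further.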

How the results depend on the processing

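Adjustments for GC and for -log10 q were chosen after the data were seen. No paired analysis was possible because the lists hold no values per replicate, and leaving out each replicate could not be run for the same reason. Over the main results 105 alternatives kept direction and side of the threshold, or about the same count, though not always the size: H3K27ac control-only peaks in PML domains went from 7.56 to 3.78 points at equal -log10 q, and control H3K9me3 coverage from 32.0 to 55.0 at equal GC. Another 19 moved a count, 5 brought a result past the threshold with its sign kept, 1 took it below, and 8 reversed the sign. Of these 8, 4 also took a result below the threshold and 1 brought one past it. A named gene with no promoter peak left under a setting has no value there. With -log10 q of at least 5 in both lists, 6 of 11 and 23 of 28 named H3K4me3 genes (control-only, knockdown-only) and 16 of 26 and 26 of 33 named H3K27ac genes stayed. With fold enrichment of at least 5 they were 3, 19, 10 and 18, and with 500 bp around the start 11, 22, 23 and 29. PML overlap with control LMNB1 and H3K9me3, the LMNB1 and H3K9me3 retention shares and the LMNB1 inside-outside difference were among those that held under each alternative run.

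The H3K9me3 inside-outside difference of -38.0 points held with long domains, joined domains, autosomes only and labels shuffled between whole domains, but over regional GC it was 0.46, 3.02 and 0.019 points with windows of 100, 500 and 2000 kb (permutation p 0.849, 0.169 and 0.994). Knockdown H3K9me3 coverage inside minus outside PML domains passed the threshold at equal GC (29.1 points, against 1.99). Control-only peaks in PML domains were no longer past it at equal GC (1.97 points for H3K4me3, from 18.3 ± 2.65, and -0.19 for H3K27ac, from 7.56 ± 1.14). The knockdown-only difference for H3K4me3 passed the threshold with -log10 q of at least 5 (2.45, permutation p 0.0225) and with sharing within 1 kb (2.71, permutation p 0.0204), and was -0.32 with equal numbers and -10.2 at equal -log10 q. For H3K27ac it was 0.59 with -log10 q of at least 5, past the threshold with equal numbers (-1.80, permutation p 0.0130), -6.08 at equal -log10 q and 0.51 at equal GC.

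Counts depended on the threshold. With equal numbers, H3K4me3 gave 982 control-only and 2611 knockdown-only peaks, and 68 and 220 promoters. With -log10 q of at least 5 against the full other list it gave 115 and 4349 peaks and 8 control-only promoters, and H3K27ac 971 and 2746 peaks and 63 and 422 promoters. With fold enrichment of at least 5 in both lists, promoters came to 35 and 694 for H3K4me3 and 200 and 1545 for H3K27ac, and H3K27ac control-only peaks to 2016. H3K27ac gene lists above the central 95%, 2 in each direction, came to 1 for losses with -log10 q of at least 5, and to 1 for gains with equal numbers or with 2500 bp around the start. The cause of these changes was not tested. Read depth, which is unknown, limits every count of weak peaks.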

Other observations

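Chosen only after the result was seen were the tests of retention by score per kb and by regional GC decile, the first adjustment for GC in 1 kb bins, the 100 and 2000 kb windows of regional GC, and the LMNB1 share in lost H3K9me3 sequence. The requirement that a remaining difference exceed its bound by more than its SE was also added after first values were seen.

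Less H3K9me3 domain length was listed after PML knockdown. Whether the coarser grid of the knockdown list contributes stays open: 0.456% of the lost length lay in control domains shorter than the shortest knockdown domain, but the control list holds too few such domains for a high share. The quartile of control length with the highest score per kb was kept by 66.7 points more than the lowest. Weak domains falling under the caller's threshold could give this, although by total score the gap was 19.4 points, between the bounds set beforehand. From the lowest quartile of score per kb, kept shares were 20.5%, 17.9%, 53.9% and 87.2%. Mean GC was 38.7%, 38.7%, 41.5% and 43.7%, so the gap by score per kb cannot be told from one by GC. The highest decile of regional GC was kept by 92.0 points more than the lowest, which may come from poorer recovery of AT-rich sequence in the knockdown H3K9me3 libraries or from a change of AT-rich heterochromatin in the cells. LMNB1 was kept over 93.0% of its control length in the lost H3K9me3 sequence. The LMNB1 lists come from other libraries, and a domain that stays listed does not measure recovery, so this does not separate these explanations. Separating them needs read coverage, which was not used here.

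Lower H3K9me3 retention inside PML domains may follow from regional GC content. Adjusting for quartiles of score per kb left -28.9 ± 4.14 points, so this measure at that resolution does not account for the difference. Each domain has 1 score, so strength within a domain or within a quartile was not adjusted for, and its part stays open. Regional GC left 3.02 ± 2.13 points, and regional GC with score per kb -0.69 ± 2.45 points. GC in 1 kb bins left -27.8 points, and with score per kb -22.5 points, but a 1 kb value misses the composition of a domain, as the regional value shows, so these exclude nothing. Retention was lower inside PML domains in 2 of the 10 GC deciles, the second (2.36% against 4.11%) and the highest (83.6% against 95.6%). An effect of PML in the lowest decile, 99.3% of which lies inside PML domains, stays open. The same holds for deciles 2 to 4. At least 83.3% of each lay inside PML domains and at most 10.4% of each was kept. Little length outside was left for comparison there, and little room for lower retention inside.

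More H3K4me3 peaks in the knockdown list may come from stronger enrichment lifting weak peaks over the threshold, since knockdown-only peaks had a median rank of 14.9% from the bottom of that list. A gain of weak sites in the cells would give the same ranks and was not tested.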
